A study of Mus musculus with 6 samples.

How the data were processed

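RNA from the aortas of 20-week-old mice on a C57BL/6 background was measured on 6 Affymetrix whole-transcript arrays, 1 array per sample. Per the labels, total RNA was amplified with a whole-transcript kit, fragmented and labelled with biotin. The sample labels give 3 arrays of Apoe knockout mice (ApoE-KO) and 3 of mice lacking both Adora1 and Apoe (DKO), numbered as replicates 1 to 3 in each group. The series text names the comparison group differently, as mice lacking Adora1, while the title, source and genotype labels of each of its samples name Apoe, and the sample labels were followed. No array was left out.

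The values are log2 intensities that the authors deposited as 1 table of 25254 probe sets, and RMA and Partek stand in the submitters' processing notes without versions. Those notes name the mouse build mm9. RMA usually includes background correction, quantile normalization and summarization of probes, and whether a batch effect was also removed is not given in the sources used here. Array medians lay between 8.01 and 8.02 and values between 2.35 and 14.9, and correlations between arrays ran from 0.983 to 0.995, so no array was a copy of another. The precision is limited by the number of arrays, and an exact permutation test of 3 against 3 cannot go below 0.1.

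Probe sets were named with the platform's annotation: 21496 name 1 gene, 1565 name several and 2193 name none, which leaves those unnamed here. No gene was named from a probe set with several. The Entrez identifiers of 21415 of the 21496 were found in a RefSeq gene table of assembly GRCm38.p6, and 0 symbols changed. That table was used only for names and for which genes neighbour each other, and no coordinates are given because the submitters' notes name another build. Of 19752 genes with a probe set of their own, each was represented by the probe set with the highest mean over the 6 arrays. Adora1 and several other listed genes are not analysed here, and 662 of the 740 genes in the lists have a probe set. A further 326 probe sets share their values with an earlier one and count separately in the totals.

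All 25254 probe sets were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), DKO minus ApoE-KO, with two-sided p-values adjusted by Benjamini-Hochberg at a threshold of 0.05 and no filter on low values. The fit without pairing was set as the first one, because the study's own ANOVA had the array batch as a factor but no label names a batch. Whether the replicate numbers pair the samples was checked on each array's deviations from its group mean before any calls were compared. Same-numbered arrays of the 2 groups correlated at 0.60, 0.50 and 0.64 over all probe sets, where unpaired arrays give 0 on average. Other combinations ran from -0.53 to -0.10, but deviations sum to 0 within a group, so positive same-number values push the others below 0 on average, and their sign is not independent evidence. These correlations are across genes, which are not independent replicates, and carry no p. The numbers were therefore taken as pairs on the evidence of the data, since no label says what a number shares, and values with the replicate number as a block are given beside each result whose call they change. Intervals are 95% intervals of the limma fits.

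Before the data were examined, 41 gene lists (cell types of the artery wall and of neighbouring tissues, and pathways) and a rule for naming genes were fixed. With under 20 probe sets passing, the rule names, per direction, 10 genes by smallest unadjusted p among those with an absolute log2 difference of at least 0.5. Where a fit passes more, it names the 12 highest and 12 lowest, and it was applied to the paired fit as well. Per list described, it names up to 4 members by smallest unadjusted p. Predicted genes and olfactory receptor genes were counted and not named. Lists were tested with camera of limma at a preset correlation between genes of 0.01 against all probe sets naming 1 gene, with camera at an estimated correlation and with fry beside it. Members were also adjusted over the list alone.

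Probe sets near Adora1, within 10 Mb on its chromosome in the RefSeq table, were compared with all other placed ones by Fisher's exact test on the share at an unadjusted p under 0.05, and with windows of the same size stepped by 2 Mb along the genome. Alternatives were the replicate block, unmoderated linear models with and without it, a SAM-type statistic, filters at the 40th and 60th percentile of the mean, renewed quantile normalization, median centring, eBayes without trend or with the robust option, array weights, probe sets naming 1 gene, rank-based camera, windows of 5 and 20 Mb, an unadjusted threshold of 0.01, and each array left out in turn. Leaving out 1 array breaks its pair, so levels shared by a replicate number enter those unpaired differences. The limma calls, camera at the preset correlation, the SAM-type statistic and the window test were tested on simulated data. These data had the real means and spreads, and 200 probe sets had been changed. Without the block, 36% of those changed by 0.50 (log2), 72% of those changed by 1.00 and 98% of those changed by 2.00 were called, with 2 false calls among 25054 unchanged probe sets. With the block these shares were 28%, 60% and 94%, with 3 false calls. The simulation took the spread estimated for each probe set as its true spread and drew probe sets independently. In the real arrays the order was the reverse, with 44 probe sets passing with the block and 0 without. The simulated shares therefore do not give the power of either fit on the real arrays. Figures were drawn with matplotlib 3.10.9.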

Results

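Aortic gene expression was compared between 3 mice lacking both Adora1, which encodes the adenosine A1 receptor, and Apoe (DKO) and 3 mice lacking Apoe alone (ApoE-KO), an atherosclerosis-prone strain. All mice were 20 weeks old. The comparison asks how the aortic transcriptome differs when Adora1 is missing in addition to Apoe. Each array gave log2 intensities for 25254 probe sets, and no wild-type or Adora1-only sample was among the 6.

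Adora1, the gene that sets the groups apart, is not analysed here, so its level could not check the labels. Apoe, which encodes the apolipoprotein that both groups lack per their labels, had a level of 9.72 ± 0.29 (SD, n = 3) in ApoE-KO and 9.58 ± 0.17 (SD, n = 3) in DKO. The single arrays read 9.47, 9.64 and 10.04 in ApoE-KO and 9.39, 9.63 and 9.72 in DKO. The difference of -0.14 (95% interval -0.52 to 0.25) was not larger than the spread between replicates (limma, adjusted p = 0.935). Without a wild-type array, and with the position of the probes relative to the deletion unknown, these levels do not check the Apoe knockout.

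The largest differences among named genes were in Retn, the adipocyte hormone resistin, at 10.74 ± 0.30 in ApoE-KO against 9.20 ± 0.26 in DKO (SD, n = 3 each), and in Kcnj15, an inward-rectifier potassium channel, at 8.33 ± 0.33 against 9.84 ± 0.42. With arrays paired by replicate number, Retn fell by 1.53 (log2; limma, adjusted p = 0.0227) and Kcnj15 rose by 1.52 (adjusted p = 0.0166). Thrsp, a nuclear regulator of fatty acid synthesis, fell by 1.32, and Pcx, the pyruvate carboxylase that feeds lipogenesis and gluconeogenesis, fell by 1.07 (adjusted p = 0.0467 and 0.0166). Without the pairing no gene passed.

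Other genes that fell in the paired fit included Acsm3, a mitochondrial acyl-CoA synthetase (-1.16), Car3, a carbonic anhydrase abundant in fat and muscle (-0.90), Cidec, a lipid droplet protein (-0.74), and Lgals12, a galectin of adipocytes (-0.68). Mmp3, the matrix protease stromelysin, fell by 0.98 from a high level of 11.61 ± 0.25 (SD, n = 3), and Orm1, an acute-phase plasma protein, fell by 0.97. The homeobox gene Hoxc6 (-0.71), the cell adhesion gene Cadm3 (-0.70) and the organic anion transporter Slco2b1 (-0.64) completed the 12 lowest. The Cidec difference moved to -1.17 without ApoE-KO replicate 1, -0.40 without ApoE-KO replicate 2 and -0.41 without DKO replicate 1. That of Lgals12 moved to -0.42 without ApoE-KO replicate 2, and none passed unpaired. Leaving out 1 array breaks a pair, so these shifts include levels shared by a replicate number. The pairs stood at -0.55, -0.74 and -0.94 for Cidec and at -0.58, -0.64 and -0.81 for Lgals12. Passing in the paired fit itself favours pairs that agree. In that fit, adjusted p-values of the genes in this paragraph ran from 0.0166 for Mmp3 to 0.0467 for Cidec, Hoxc6, Cadm3, Lgals12 and Slco2b1.

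Among the genes that rose in the paired fit, Upk1b, a uroplakin also made by mesothelium (1.19), Lrrn4, a mesothelial membrane protein (0.80), and Gpm6a, a membrane glycoprotein (0.69), were joined by Angptl7, a secreted angiopoietin-like protein (1.01). Epyc, a small leucine-rich proteoglycan of cartilage, and Tbx20, a T-box factor of heart development, each rose by 0.88, and Olfml2a, an extracellular olfactomedin-like protein, rose by 0.58. Phex, an endopeptidase that regulates phosphate handling, rose by 0.76, Ctse, the protease cathepsin E, by 0.79, Sphkap, an anchoring protein for protein kinase A, by 0.85, and Snrpe, a core spliceosomal protein, by 0.75. Adjusted p-values ran from 0.0166 for Kcnj15 to 0.0470 for Gpm6a.

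**Figure D1:**
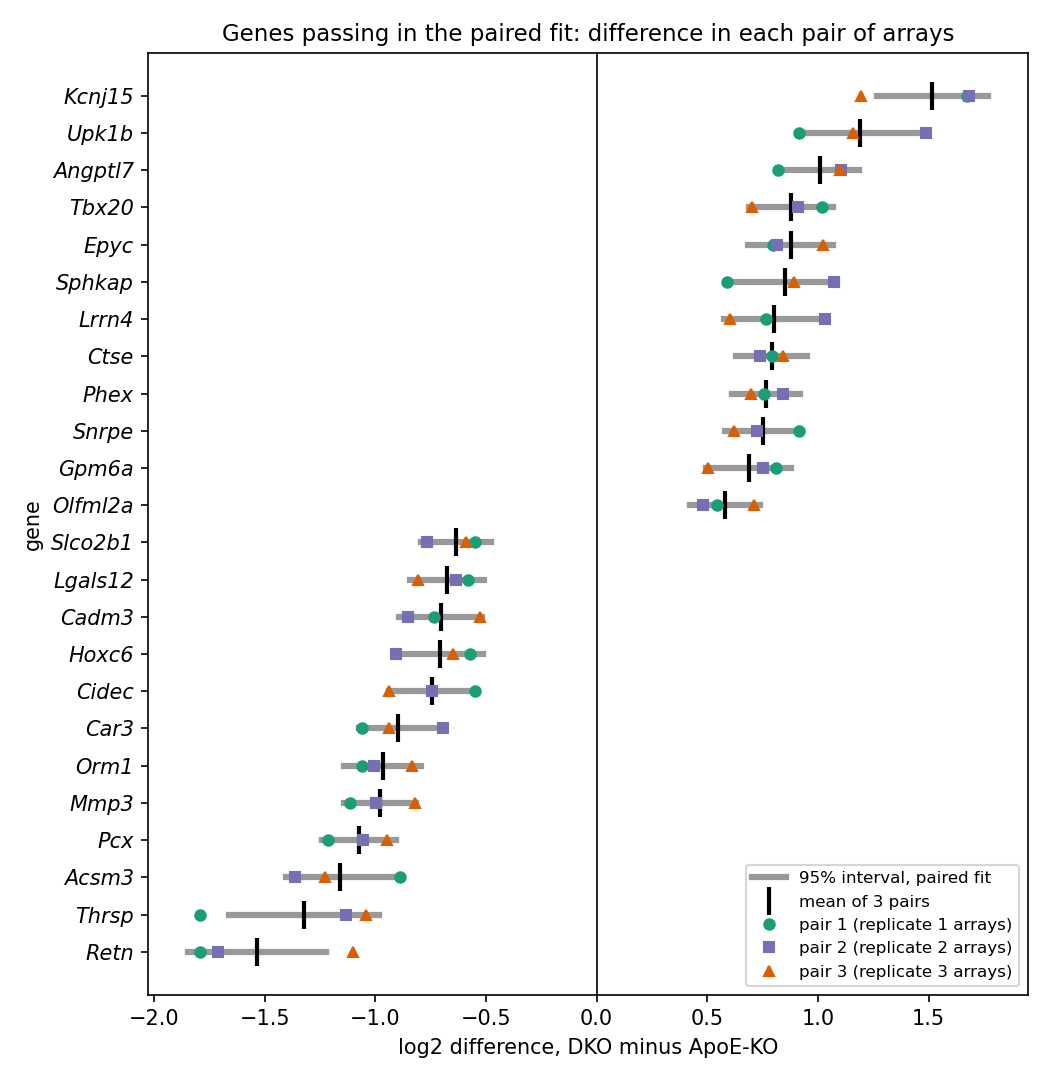
Log2 difference, DKO minus ApoE-KO, for the 12 highest and 12 lowest named genes that passed in the paired fit. Coloured points are the 3 pairs of arrays with the same replicate number, black bars the mean of the pairs and grey bars the 95% interval of the paired limma fit; the means run from -1.53 for Retn to 1.52 for Kcnj15.

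Among genes that passed in neither fit, the naming rule added, on the higher side, Nnt, the mitochondrial transhydrogenase that makes NADPH (0.76, paired adjusted p = 0.0503), Rimklb, a glutamate ligase (0.73, paired adjusted p = 0.0517), Slc26a3, a chloride-bicarbonate exchanger (0.69, paired adjusted p = 0.0591), and Pde1c, a calmodulin-dependent phosphodiesterase (0.56, paired adjusted p = 0.0517). Tmtc2, of the same part of the rule, rose by 0.55 in the paired fit (adjusted p = 0.0467). On the lower side it added Fasn, the fatty acid synthase, with a difference of -1.13 (paired adjusted p = 0.0721), the vasopressin receptor gene Avpr1a (-0.66, paired adjusted p = 0.0503), the matrix protease gene Adamts15 (-0.55, paired adjusted p = 0.0628), Nxph1, a neurexin ligand (-0.53, paired adjusted p = 0.0545), and Ppa1, a pyrophosphatase (-0.52, paired adjusted p = 0.0551). In these 9 genes the groups did not overlap, which is no support, since they were chosen by smallest p. Over all 25254 probe sets the groups did not overlap in 3035.

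Over all probe sets, limma without the pairing passed 0 of 25254 (smallest adjusted p = 0.235), with 1419 at an unadjusted p under 0.05, 743 of them higher in DKO, where chance gives 1263. With the replicate block 44 passed, 24 higher and 20 lower in DKO, and 4092 had an unadjusted p under 0.05. Of the 44, 35 name 1 gene, 4 several and 5 none. The groups did not overlap in 3035 probe sets, while chance gives 10% for exchangeable arrays. Both chance values ignore the pairing: the 3 other splits that part every pair gave 981 to 1258 probe sets without overlap and 240 to 393 at an unadjusted p under 0.05. The SAM-type statistic passed 24, of which 15 were among the 44. Without the array of DKO replicate 3, the unpaired fit passed 8, of which 2 were among the 44, and with the block but without pair 2 of the arrays 0 passed.

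White adipose tissue genes had the smallest adjusted p of the 41 gene lists with camera at the preset correlation, though not with fry or an estimated correlation. Of 14 measured members 13 were lower in DKO, with a mean difference of -0.45 ± 0.08 (SD over 3 pairs), which ran from -0.28 without DKO replicate 1 to -0.63 without DKO replicate 2. Beside Retn and Car3, the members with the smallest p were Dgat2, which completes triglyceride synthesis (-0.58), and Agt, the angiotensin precursor (-0.23). Lymphatic endothelium genes were lower in 6 of 6 members (mean -0.44 ± 0.17, SD over 3 pairs), with the vessel marker Lyve1 at -0.61, the matrix protein gene Mmrn1 at -0.86, Reln, which encodes reelin, at -0.39, and Flt4, the lymphatic growth factor receptor, at -0.32. Both lists passed with camera (limma; adjusted p = 1.07e-05 and 1.43e-05) and did so with the replicate block (adjusted p = 1.91e-11 and 6.95e-06). With an estimated correlation neither passed (adjusted p = 0.971 and 0.834).

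In the paired fit and adjusted over the list alone, 13 adipose members fell and 1 rose, the rise being that of Lep, the leptin gene (0.36), named here after its value was seen. Over all genes 3 fell, Retn, Car3 and Cidec, and 11 did not pass. Of the lymphatic members, 5 fell and 1 did not pass adjusted over the list alone, and over all genes 1 fell, Lyve1. Without pairing, 1 adipose member, Retn, and 2 lymphatic members fell when adjusted over the list alone, and 0 passed over all genes.

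Heat shock and unfolded protein response genes were lower in 13 of 18 members (mean -0.19 ± 0.12, SD over 3 pairs). The members with the smallest p serve protein folding in the endoplasmic reticulum or the stress response: Sdf2l1 (-0.72), Asns, the asparagine synthetase (-0.43), and the chaperones Hspa5 (-0.37) and Hsp90b1 (-0.26). Camera passed the list without and with the block (adjusted p = 0.000486 and 0.000292), and with an estimated correlation it did not pass (adjusted p = 0.834). Adjusted over the list alone, 4 members fell and 14 did not pass in the paired fit, and 0 passed over all genes or without pairing.

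Mast cell genes were lower in all 8 members (mean -0.23 ± 0.02, SD over 3 pairs), led by Cpa3, the granule carboxypeptidase (-0.78), Kit, the stem cell factor receptor (-0.31), Fcer1a, a subunit of the IgE receptor (-0.15), and Cma1, a chymase (-0.11). The list passed with camera and with the block (adjusted p = 0.0224 and 0.00247), not with an estimated correlation (adjusted p = 0.971), and not without ApoE-KO replicate 3 or DKO replicate 1 (means -0.19 and -0.15, adjusted p = 0.164 and 0.127). Nor did it pass above the 40th percentile, after quantile normalization, with array weights or without both replicate 3 arrays (adjusted p = 0.0654, 0.0756, 0.0564 and 0.0819). In the paired fit 3 members fell adjusted over the list alone, 5 did not pass, and 0 passed over all genes or without pairing.

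Mesothelium and epithelium genes were higher in DKO in 9 of 13 members (mean 0.30 ± 0.26, SD over 3 pairs): Upk3b, a uroplakin of mesothelium (1.44), Upk1b, Lrrn4, and the keratin gene Krt18 (0.73). Camera passed the list (adjusted p = 0.00123), but not with the replicate block (adjusted p = 0.0746), with an estimated correlation (adjusted p = 0.971), with ranks (adjusted p = 0.103) or without ApoE-KO replicate 1 (mean 0.046, adjusted p = 0.0836), and its mean was 0.79 without ApoE-KO replicate 3. Adjusted over the list alone, 5 members rose and 2 fell in the paired fit, and 2 rose over all genes, Upk1b and Lrrn4; without pairing, 5 rose and 1 fell adjusted over the list alone and 0 passed over all genes. Without DKO replicate 3 the list's mean was -0.05 while camera still gave a higher list, and 2 of its members, the lung genes Sftpc and Scgb1a1, stood far higher in both replicate 3 arrays: Sftpc at 12.32 in ApoE-KO and 11.92 in DKO against 6.21 to 6.45 elsewhere, and Scgb1a1 at 13.70 and 12.93 against 5.40 to 5.97.

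Adenosine signalling genes other than the receptors were higher in 14 of 16 members (mean 0.15 ± 0.07, SD over 3 pairs). They included Rgs4, which shortens signalling by G proteins (0.63), Nt5e, the ectonucleotidase that makes adenosine from AMP (0.29), Gnao1, a G protein subunit (0.18), and the phosphodiesterase gene Pde4b (0.16). The list passed with camera without and with the block (adjusted p = 0.00227 and 0.000360), not with an estimated correlation (adjusted p = 0.834), and not without ApoE-KO replicate 2 (mean 0.093, adjusted p = 0.0870). Adjusted over the list alone, 1 member, Rgs4, rose in the paired fit, 15 did not pass, and 0 passed over all genes or without pairing.

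A further 3 lists passed with the block only. Schwann cell and neuron genes had a mean of -0.22 ± 0.22 (SD over 3 pairs; adjusted p = 0.0635 without and 0.0244 with the block), complement genes -0.14 ± 0.27 (adjusted p = 0.222 and 0.00978) and skeletal muscle genes -0.11 ± 0.17 (adjusted p = 0.412 and 0.0236). With an estimated correlation and the block none of them passed (adjusted p = 0.937 for each). The complement pairs stood at -0.45, 0.021 and 0.017, so the fall in that mean came from pair 1. The skeletal muscle pairs stood at 0.058, -0.11 and -0.28. Lower in DKO were 11 of 14 nerve, 13 of 14 complement and 14 of 15 skeletal muscle members. Among those with the smallest p in nerve, Tubb3, a neuronal tubulin (-0.32), Nefm, a neurofilament (-0.32), and Cdh19, a glial cadherin (-0.54), were lower and Uchl1, a neuronal hydrolase, was higher (0.25). In muscle, the myosin gene Myh1 (-0.19), the troponin gene Tnnt3 (-0.23) and the actin gene Acta1 (-0.24) were lower, and Mybpc2, a myosin-binding protein (0.15), was the only higher member. In complement, the components C2 (-0.43), C6 (-0.26) and C4b (-0.37) and the receptor gene C3ar1 (-0.22) were lower, and in the paired fit C2 was the only one of the 43 members to fall when adjusted over the list alone, with 42 not passing and 0 passing over all genes. Without DKO replicate 1 the complement mean was 0.11, and the skeletal muscle mean turned to 0.16 without ApoE-KO replicate 3 and to 0.0056 without DKO replicate 2. The unpaired call appeared for complement without ApoE-KO replicate 1, DKO replicate 2 or DKO replicate 3, and for skeletal muscle without ApoE-KO replicate 1 or DKO replicate 3 (adjusted p from 0.000116 to 0.0404). Schwann cell and neuron genes passed unpaired without ApoE-KO replicate 1 (-0.32), ApoE-KO replicate 2 (-0.29), DKO replicate 2 (-0.21) or DKO replicate 3 (-0.26), with adjusted p from 0.00592 to 0.0412. Their mean was -0.048 without ApoE-KO replicate 3 and -0.18 without DKO replicate 1 (adjusted p = 0.583 and 0.184), and the pairs stood at -0.09, -0.09 and -0.47. The members Th and Dbh, of catecholamine synthesis, read 9.26 and 8.37 in ApoE-KO replicate 3, against at most 7.71 and 6.51 elsewhere.

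Macrophage and foam cell genes had a mean of -0.09 ± 0.53 (SD over 3 pairs) and did not pass in either fit (adjusted p = 0.653 without and 0.483 with the block). The pairs disagreed, at -0.69, 0.29 and 0.13, and without DKO replicate 1 the list was higher in DKO (0.21, adjusted p = 4.17e-05) while without DKO replicate 2 it was lower (-0.32, adjusted p = 0.000116). Adhesion molecules and chemokines behaved alike, with a mean of -0.03 ± 0.31 (SD over 3 pairs; adjusted p = 0.231), 0.13 without DKO replicate 1 and -0.14 without DKO replicate 2 (adjusted p = 0.122 and 0.000486), and -0.071 without DKO replicate 3 (adjusted p = 0.0309); 1 of their 29 members fell when adjusted over the list alone, the monocyte chemokine gene Ccl7 (-0.46). Contractile smooth muscle genes (mean 0.07 ± 0.04, SD over 3 pairs; adjusted p = 0.138) and cell cycle genes (-0.03 ± 0.02; adjusted p = 0.784) did not pass, though the contractile list did without ApoE-KO replicate 1 (0.12, adjusted p = 0.0116).

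In all, 6 of the 41 lists passed with camera at the preset correlation and 8 with the block, of which 5 were among the 6. With an estimated correlation and with fry 0 passed, with or without the block. Neither of these was run on the simulated data. Whether they can pass any list with 6 arrays is therefore unknown, and 0 passing does not by itself count against a list. Leaving out ApoE-KO replicate 1, DKO replicate 1, 2 or 3 gave 10, 10, 13 and 11 lists with camera at the preset correlation. With the same preset-correlation test, every other split of the 6 arrays into groups of 3 passed more lists than the real one, 12 to 24, so a list passing that test does not by itself set the genotypes apart.

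**Figure D2:**
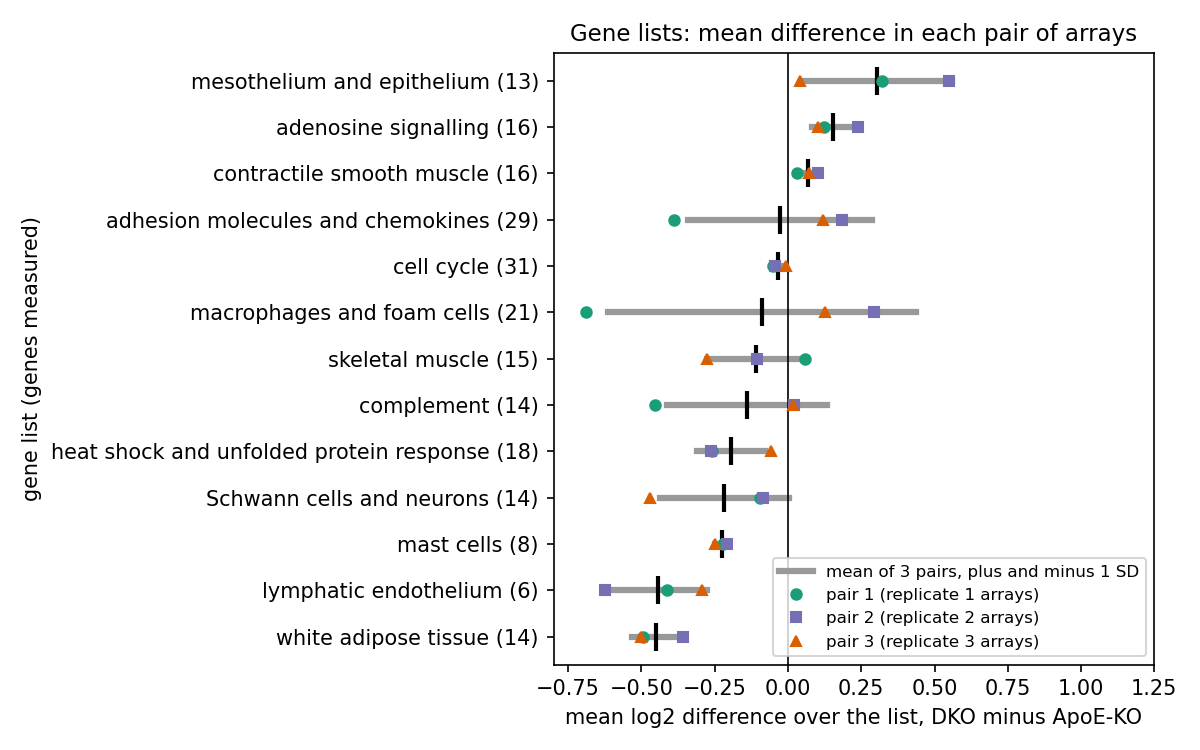
Mean log2 difference over the members of 13 gene lists, DKO minus ApoE-KO, in each of the 3 pairs of arrays with the same replicate number (coloured points). Black bars are the mean of the pairs and grey bars 1 SD to each side; the white adipose list lies below 0 in every pair, while the macrophage list ranges from -0.69 to 0.29.

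Genes near Adora1 differed between the groups more often than genes elsewhere. Within 10 Mb of it in the RefSeq table of assembly GRCm38.p6, 17 of 155 probe sets (10.97%) had an unadjusted p under 0.05, against 5.81% of the other 21260 placed ones (odds ratio 2.0, 95% interval 1.13 to 3.33; Fisher's exact test, two-sided, p = 0.0142). Of the 17, 6 were higher in DKO, among them Ctse, Snrpe, Lypd1, a membrane-anchored protein (0.68), and Lgr6, a stem cell receptor (0.39), and 11 were lower, among them Gpr37l1, a glial receptor (-0.43), and Mcm6, a replication helicase subunit (-1.07). The Mcm6 difference rested largely on DKO replicate 1, at 6.68 against 8.17 and 7.98 in the other DKO arrays, and was -0.60 without it. These genes other than Ctse and Snrpe were named after their values were seen. None passed over all genes without pairing, and in the paired fit Ctse and Snrpe rose. With the replicate block the excess was no longer significant (34 of 155, 21.9% against 16.7%, odds ratio 1.40, 95% interval 0.92 to 2.06, exact p = 0.104). Nor was it within 20 Mb (odds ratio 1.29, exact p = 0.261) or without DKO replicate 1 (odds ratio 1.71, exact p = 0.0826). These settings do not show that the excess is absent. Adjusted over the window alone, 8 probe sets passed in the paired fit and 0 without pairing. Other windows were not adjusted in this way.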

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

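The fits with pairs of arrays left out, those with an estimated correlation or fry and the block together, and the fit without both replicate 3 arrays were added after seeing the data. Adora1 has no value here under any setting, and the alternatives set beforehand for the other results were all run. The number of genes passing was 0 without pairing and 0 with the unmoderated model with replicate block (2669 at an unadjusted p under 0.05), with the filters, either rescaling, eBayes without trend or with the robust option, array weights, probe sets naming 1 gene, and both replicate 3 arrays left out. It was 44 with the replicate block, 1 with the unmoderated model of genotype alone, 24 with the SAM-type statistic, 0 to 8 with single arrays left out, and 415, 0 and 48 with the block and pair 1, 2 or 3 left out. The 44 were all among the 415, and 24 were among the 48. The direction of all 44 held under each setting that kept them. For the 34 named genes the block passed 25, or 34 and 20 with pair 1 or pair 3 left out, and no alternative turned a direction. Kept directions are no support, for the 44 or the 34. Both sets were chosen by p-values from these same arrays, and several settings reuse the same differences. Apoe passed nowhere, and its difference ran from -0.26 to 0.024 with single arrays left out, turning its sign without ApoE-KO replicate 3. The 6 lists became 0 with an estimated correlation and 0 with fry, each without and with the block, 16, 15 and 12 with the block and pair 1, 2 or 3 left out, and 6 to 13 with single arrays left out. The odds ratio near Adora1 was no longer significant with the replicate block (1.40), within 20 Mb (1.29) and without DKO replicate 1 (1.71). Single arrays left out gave 1.63 to 3.97. Both rescalings shifted the median of all probe sets by under 0.01 (log2).

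An estimated correlation and fry change the test and not the means, so the lists for white adipose tissue (-0.45), lymphatic endothelium (-0.44), heat shock (-0.19), mesothelium (0.30), adenosine signalling (0.15) and mast cells (-0.23) kept these means while no longer passing, with adjusted p from 0.137 to 0.971. White adipose, lymphatic and heat shock lists passed under every other setting, with means of -0.63 to -0.28, -0.54 to -0.32 and -0.26 to -0.16. The mesothelium list no longer passed with the block or with ranks (0.30), or with the block and pair 1 (0.30) or pair 2 (0.18) left out, and single arrays left out gave -0.050 to 0.79. Adenosine signalling ran from 0.093 to 0.22 with single arrays left out. The mast cell list no longer passed above the 40th percentile (-0.32), after quantile normalization (-0.21), with array weights (-0.21) or without both replicate 3 arrays (-0.21), and ran from -0.31 to -0.15 with single arrays left out. Lists that gained a call were Schwann cells and neurons with the block (-0.22) and with pair 1 (-0.28) or pair 2 (-0.28) also left out, from -0.32 to -0.048 with single arrays left out; complement with the block (-0.14) and without pair 2 (-0.22) or pair 3 (-0.22), reversed without pair 1 (0.019), from -0.32 to 0.11; and skeletal muscle with the block (-0.11) and without pair 1 (-0.19) or pair 2 (-0.11), from -0.29 to 0.16. Contractile smooth muscle passed with the block and pair 1 left out (0.087), and ran from 0.032 to 0.12. The macrophage list reversed with array weights (0.11) and with the block and pair 1 left out (0.21), passed without pair 2 (-0.28), and ran from -0.32 to 0.21. Adhesion molecules reversed with array weights (0.087) and with the block and pair 1 left out (0.15), passed above the 40th percentile (-0.041), with the block and pair 2 (-0.13) or pair 3 (-0.10) left out and without both replicate 3 arrays (-0.10), and ran from -0.14 to 0.13. The cell cycle list ran from -0.075 to -0.0070, and camera's direction turned without ApoE-KO replicate 1, ApoE-KO replicate 2 or DKO replicate 3. The block changed no other call of a result named here. Apart from fewer arrays or a changed test, the cause was not tested.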

Other observations

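The tests on splits of the arrays and on adipose tissue and the fit without pair 3 were chosen after the results were seen, while the share of lung genes and the windows for donor-strain DNA were set before their outcome was looked at. Among the genes that passed in the paired fit outside the naming rule, chosen after their values were seen, the muscle ubiquitin ligase gene Fbxo32 rose by 0.46, the GTPase gene Rrad by 0.48, Tceal1, a transcription elongation factor-like gene, by 0.57, and Atp1b2, a subunit of the sodium pump, by 0.55. Gpx3, the glutathione peroxidase of plasma, fell by 0.52 from a level of 12.20 ± 0.43 (SD, n = 3), Igfbp3, which binds insulin-like growth factors, fell by 0.56, and the matrix protein gene Sned1 fell by 0.58. Their adjusted p-values (limma with the replicate block) ran from 0.0467 to 0.0483, and none passed without pairing.

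A group of 9 probe sets that name no gene here had the largest differences of the table, from -3.56 to -3.14. Their median was 9.35 in the ApoE-KO arrays and 5.08, 5.48 and 7.52 in DKO 1, 2 and 3. None passed without pairing (limma, smallest adjusted p = 0.468), and 3 passed with the block. The Y-linked genes Kdm5d, Uty and Eif2s3y lay between 8.47 and 9.74 in all 6 arrays and Xist between 6.19 and 6.67.

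The 6 arrays allow 10 splits into groups of 3, and the 3 pairs allow 4 assignments, too few for a share under 0.05. Without pairing the real split passed 0 probe sets and the highest other 0, so all 10 of the 10 splits gave as many. With the block the real assignment passed 44 probe sets and the highest other 0, so that 1 of the 4 assignments gave as many. For the lists, all 10 splits gave at least the real 6, and the highest other gave 24. That split set ApoE-KO 3, DKO 2 and DKO 3 against the rest and parts 1 of the pairs. It is only the highest of the 10, and whether list counts follow the replicate numbers was not tested. The 3 other splits that part all pairs gave 16, 12 and 13 lists without the block and 17, 14 and 18 with it, against the real 6 and 8, and 240 to 393 probe sets at an unadjusted p under 0.05 against 1419.

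White adipose genes were lower in DKO, and a smaller share of fat around the DKO aortas is a candidate explanation. As the whole cause it would lower all 14 members by a common amount only if no other cells in the samples made them. Whether other cells did was not tested. The members' paired differences were heterogeneous, with or without Lep (permutation within pairs, p = 1e-05, the smallest that 100000 permutations allow). They ran from -1.53 for Retn to 0.36 for Lep. That test replaced Cochran's Q, run first with the same outcome, because Q treats errors from 3 pairs as known. Neither corrects for weak signals that compress a gene's difference or for signal from other cells, so neither decides on the amount of fat. With the block the list passed camera at the preset correlation only, not with an estimated correlation or fry (adjusted p = 0.937 and 0.287). The brown adipose tissue list did not pass (camera at the preset correlation, adjusted p = 0.399 without and 0.381 with the block). Its mean was -0.15, with pairs at -0.18, 0.15 and -0.40, 5 members higher and 7 lower. A part played by the amount of fat, a change of state in fat cells and the loss of Adora1 stay open, and the design cannot separate them.

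Lung transcripts stood high in both replicate 3 arrays, and lung tissue carried along at dissection is a candidate source. Of 20 further lung genes listed before their levels were looked at, 9 (45%) were higher by at least 1 (log2) in both replicate 3 arrays than in every other array, against 0.234% of all probe sets, among them Slc34a2 at 11.15 and 10.15, Cyp2f2 at 11.96 and 11.11 and Sftpb at 10.60 and 9.95. That share lies between the bounds set for and against lung tissue, so it stays open; 18 of the 20 were higher by some amount, against 9.0% of all probe sets, and 4 of the 20 had a mean above the table's median in the other arrays. With the block and pair 3 left out 24 of the 44 probe sets still passed. The other 20 kept 0.87 to 1.09 times their differences while their median standard error rose from 0.066 to 0.087. In the 24 that held it also rose, from 0.081 to 0.093. With all pairs, the median absolute difference was 0.99 in those 24 and 0.58 in the 20. What ended the 20 calls was not tested. The 44 had been selected for agreement of the pairs. That selection itself favoured kept differences, which therefore cannot tell for or against lung tissue. No biological explanation was tested, since both groups showed the pattern. Its size was not equal, however: all the further lung genes read higher in ApoE-KO replicate 3 than in DKO replicate 3. The gap ran from small, as in Aqp5 (8.62 against 8.56), to large, as in Lamp3 (7.80 against 6.60). The difference of pair 3 includes this imbalance.

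DNA kept from the strain in which Adora1 was disrupted may underlie the differences near that gene, because neighbouring genes can then differ by strain. The window around Adora1 had a larger share of probe sets at an unadjusted p under 0.05 than 95.6% of the 1150 other windows, above the bound of 95% set for it, but than 81.5% with the replicate block. The same was asked for Nnt, which carries a deletion in some C57BL/6 sublines and was higher in DKO: the window around it, Nnt left out, exceeded 73.7% of the other windows, between the bounds set, so donor DNA there stays open. A difference between C57BL/6 sublines, an effect of Adora1 loss on its neighbours and the few arrays were not separated by any test here.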
